A study of Homo sapiens with 8 samples.

How the data were processed

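Total RNA was sequenced from 8 cultures of SV-HUC1, an established line of normal human urothelial cells immortalised with SV40. Per the labels, 4 cultures were untreated controls and 4 were kept with glucose oxidase, an enzyme that makes hydrogen peroxide from glucose, at 20 mU per ml for 24 h. Libraries of each group carry the replicate numbers 1 to 4, and the design text of the series speaks of independent experiments without saying that equal numbers mark the same experiment.

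Per the submitters' processing notes, the authors used HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the build GRCh38.p13. The strand setting of the counting is not given in the sources used here, so it is not known whether reads of overlapping and antisense genes were told apart. The deposited counts are whole numbers per gene, not normalised, for 58735 genes whose identifiers, names and coordinates all equal those of GENCODE release 29. The deposited FPKM values were scaled by the authors' size factors, since in the values each library's FPKM denominator is its size factor times a single constant. The deposited comparison table holds the authors' size-factor-normalised signal as a mean per group, their log2 fold change, and their p-value and adjusted p-value, in rows for 36644 genes. The p-value is empty for 4 of these and the adjusted p-value is 1 for 17765. The smallest p-value times 18879 gives its deposited adjusted p-value. DESeq2 without a block, at its default filtering threshold, also gave an adjusted p-value to 18879 genes. The remaining rows thus appear to be genes left out by that filter, not genes tested and found unchanged. A gene length in bases, the summed length of all annotated exons, stands in the deposited tables and served as a covariate. No per-sample column was left unused.

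Total counts per library ran from 21437267 to 27183692. Counts were tested with edgeR 4.0.16 under R 4.3.3 (quasi-likelihood fit and test, TMM normalisation, filterByExpr, Benjamini-Hochberg adjusted p below 0.05), which left 17413 genes. The fit chosen before the data were examined had the group as its only term. CPM values are TMM-normalised, given as mean ± SD over 4 libraries, and fitted changes are log2 values with a standard error. Gene lists were fixed before the data were examined (29 lists, of which 25 had at least 5 tested members) and were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. Library measures were compared by an exact two-sided permutation test, whose smallest possible p is 0.0286.

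Whether the replicate numbers pair the libraries was checked from each library's deviation from its group mean of log2 CPM (prior count 2). The 4 same-number correlations across genes were 0.532, 0.678, 0.590 and 0.503, all over the minimum of 0.1 set beforehand, so the fit with the replicate number as a block is given beside the one without. That rule does not separate pairing by number from a division of the libraries into replicates 1 and 2 and replicates 3 and 4: differently numbered libraries inside these sets correlated at 0.443 to 0.652, and control 3 was closer to treated 4 than to treated 3. The difference between controls 1 and 2 correlated with that between treated 1 and 2 at 0.292, and the difference between controls 3 and 4 with that between treated 3 and 4 at -0.0355. A fit with a term for replicates 1 and 2 against 3 and 4 in place of the block was therefore added after the data were seen. That division was found from the expression values and is not in the labels.

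Within each group no 2 libraries agreed within sampling noise (chi-square per degree of freedom 10.9 to 260.2), so each counted as 1 replicate. That does not show that the cultures were independent. The value was 10.9 to 74.8 inside replicates 1 and 2 or 3 and 4, and 94.2 to 260.2 across these sets. Counts were also simulated with a mean for each replicate number that both groups shared, and with the spread of the blocked fit. Pairing by number was thus built in, which favours the block and says nothing about whether the real libraries pair. On simulated counts for 17413 genes with 200 changed, the edgeR fit without block recovered 0% of 2-fold and 59.1% of 4-fold changes, and the edgeR fit with block 91.0% and 100%, with 9 false calls. DESeq2 without block recovered 40.3% and 92.4% with 0 false calls, and with block 85.1% and 100% with 9. The fit for a difference of effects between replicates 1 and 2 and replicates 3 and 4 recovered 0% of 2-fold and 47.0% of 4-fold differences.

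Named genes followed a rule set before the data were examined. It took the 10 largest increases and 10 largest decreases among called protein-coding genes with a mean of at least 5 CPM and all treated libraries on the same side of all controls, in each list that passed camera the 4 called members of smallest adjusted p in its direction and up to 2 in the other, in other lists up to 2 in each direction (the 2 most abundant where none was called), and 13 genes named regardless of their values. The rule gave no gene of the first kind in the fit without block and was applied to the blocked fit. The alternatives were other scalings (DESeq2 1.42.0 size factors, total counts), filters, tests (DESeq2, limma-voom, limma-trend on log2 of FPKM plus 1 or plus 0.1 with a mean FPKM of at least 0.5), libraries left out in turn, and corrections for GC content, for summed exon length and for the length of the principal transcript (loess of each library, span 0.5). DESeq2 was run at a filtering threshold of 0.05 (35 genes higher and 39 lower without a block) and at the tool's own default (36 and 40). The blocked alternatives, the length and GC corrections and the pairing of control 3 with treated 4 were chosen after the data were seen.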

Results

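Gene counts were measured in 8 SV-HUC1 cultures, 4 untreated and 4 kept for 24 h with glucose oxidase at 20 mU per ml, a source of hydrogen peroxide. The comparison asks which genes of these urothelial cells change with glucose oxidase. There was no group with peroxide alone or with inactive enzyme. Effects of peroxide therefore cannot be told apart from other effects of the enzyme, such as its use of glucose. Total counts ran from 21653952 to 23543702 in controls and from 21437267 to 27183692 in treated cultures (two-sided exact permutation p = 0.171, adjusted p = 0.458 over 4 library measures). The share of counts in mitochondrially encoded genes was 2.32 ± 0.80% in controls and 2.90 ± 0.46% in treated cultures (SD, n = 4, exact permutation p = 0.229, adjusted p = 0.458). The share in the 10 most abundant genes was 5.98 ± 1.64% and 5.45 ± 0.93% (SD, n = 4, exact permutation p = 0.571, adjusted p = 0.761). Controls had 28294 ± 3051 genes detected and treated cultures 28317 ± 1589 (SD, n = 4, exact permutation p = 0.971).

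**Figure D1:**
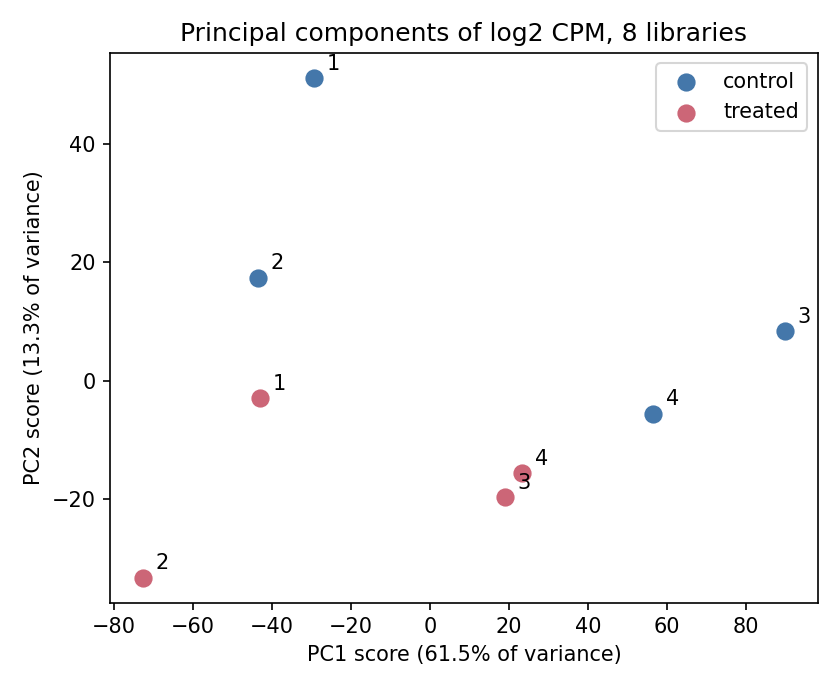
Scores of the 8 libraries on the first (61.5% of variance, x axis) and second (13.3%, y axis) principal components of log2 CPM; points are libraries, colours are groups and digits are replicate numbers. Replicates 1 and 2 of each group have negative scores on the first component and replicates 3 and 4 positive ones.

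LCN2, IL1A and other inflammatory genes were higher after glucose oxidase, and KRT13, ID4 and cholesterol synthesis genes were lower, in a fit that takes the replicate number into account. LCN2 (ENSG00000148346), an iron-binding protein of innate defence on chromosome 9 (128149071 to 128153455, GRCh38), was at 57.5 ± 11.1 CPM in controls and 184.1 ± 44.7 CPM in treated cultures (SD, n = 4), a log2 change of 1.67 (SE 0.14). KRT13 (ENSG00000171401), a keratin of stratified epithelium on chromosome 17 (41500981 to 41505705), was at 787.8 ± 255 CPM and 324.4 ± 62.3 CPM (SD, n = 4), a log2 change of -1.25 (SE 0.17). With the replicate number as a block, edgeR called 1308 genes higher and 1213 lower, of which 169 and 159 changed at least 2-fold.

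The edgeR fit chosen before the data were examined, with no block, called 0 genes in either direction. Its smallest adjusted p was 0.257, and 1284 of 17413 genes had an unadjusted p below 0.05. DESeq2 without a block called 35 genes higher and 39 lower. Because libraries of replicates 3 and 4 do not pair by number beyond their separation from replicates 1 and 2, a fit with a term for replicates 1 and 2 against 3 and 4 was set beside the block. It called 648 genes higher and 534 lower, all of them among the blocked calls. Scaling by total counts alone moved the median log2 change of all genes to 0.101 and turned the blocked calls to 1675 higher (75.8% of calls, against 51.9%) and 535 lower. Below, "rose" and "fell" are said of genes past an adjusted p of 0.05 in the blocked edgeR fit. No gene named here passed in the filtered edgeR fit without the block. With no filter on low counts, edgeR without the block called 18 genes higher and 16 lower, among them LCN2, IL1A, IL1B, GBP5 and CPA4. In the filtered edgeR fit without the block these named genes had an adjusted p of 0.257 (LCN2) to 0.644 (IL1A). Their calls thus depend on keeping genes of low counts, and why was not tested.

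Among protein-coding genes of at least 5 CPM, 199 that rose and 135 that fell had all 4 treated libraries on the same side of all controls. Over all genes tested, 5.02% were so placed, against 2.86% by chance for 8 exchangeable libraries. That chance value leaves out the separation of replicates 1 and 2 from 3 and 4. The largest increases among them were of IL1A, an alarmin cytokine (29.2 ± 28.1 to 134.0 ± 28.9 CPM, log2 change 2.83, adjusted p = 9.72e-05), GBP5 (log2 change 2.14), APOBEC3A (1.91), IL24 (1.67), LCN2, IL1RL1 (1.63), ICAM1, an adhesion molecule (1.34), TNFAIP3, an inhibitor of NF-kB signalling (1.29), CFB (1.29) and DUSP5 (1.29). The largest decreases were of CPA4 (log2 change -1.68), SLC1A6 (-1.50), PLAC8 (-1.39), COMMD6 (-1.30), ID4 (-1.26), KRT13, CALML5 (-1.16), AOC1 (-1.16), POU5F1 (-1.07) and SYT8 (-1.05). POU5F1 shares sequence with pseudogenes and its value is uncertain. All 20 also passed with the term for replicates 1 and 2 against 3 and 4. The changes of IL1A and DUSP5 differed between these sets (edgeR adjusted p of the difference 0.000445 and 0.0352). IL1A had log2 changes of 1.163 in replicates 1 and 2 and 4.735 in replicates 3 and 4, and DUSP5 0.49 and 2.19.

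The authors' deposited table listed 36 genes higher and 40 lower at an adjusted p below 0.05. DESeq2 without a block, at its default filtering threshold, called the same 76 genes. Of the 75 of these genes tested here, 75 were called by the blocked edgeR fit in the same direction. Both sets of calls come from the same 8 libraries, so the overlap is not independent support. In the authors' deposited table LCN2 had a log2 change of 1.68 (adjusted p = 2.89e-08) and HMOX1 one of 0.49 (adjusted p = 0.42).

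**Figure D2:**
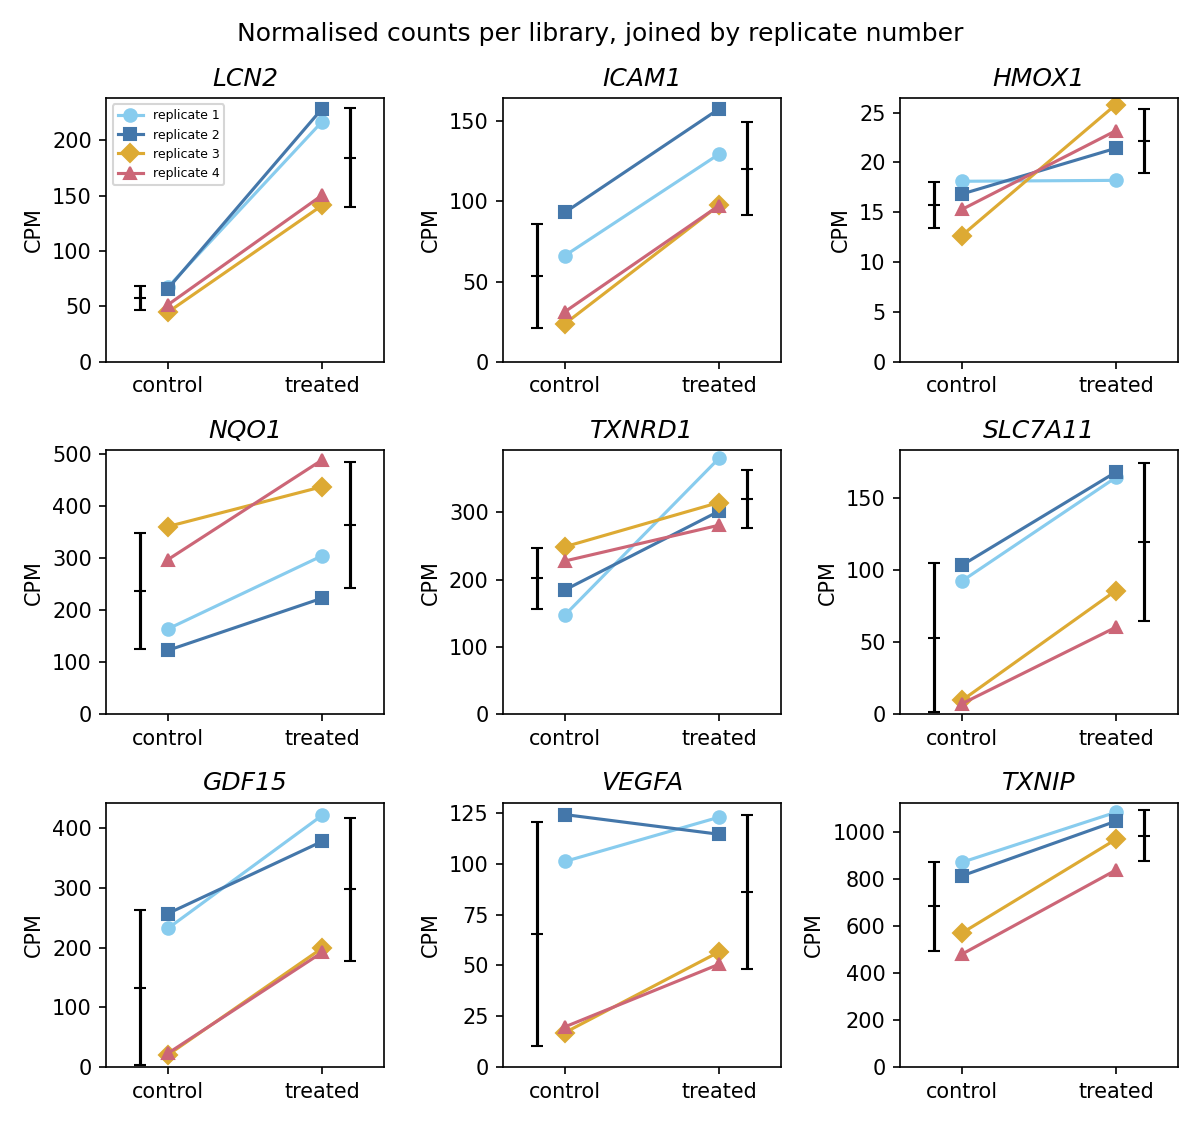
TMM-normalised CPM (y axes from 0) of 9 genes in control and treated cultures; lines join libraries of the same replicate number, and bars beside them are the mean ± SD of 4 libraries. LCN2 is higher in treated than in control cultures in each of the 4 pairs, with pair log2 differences of 1.53 to 1.78.

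Targets of NRF2, the transcription factor of the antioxidant response, were called higher as a list by camera at the preset correlation (adjusted p = 1.89e-05 without and 1.09e-05 with the block). The call was lost with an estimated correlation (adjusted p = 0.272 without and 0.398 with the block), and fry gave an adjusted p of 0.109 and 0.0204. Of 30 tested members 10 rose, 1 fell and 19 did not pass (12 and 2 adjusted over the list alone), with a median log2 change of 0.26 and pair medians of 0.25, 0.28, 0.19 and 0.27. SLC7A11, a cystine transporter, rose by a log2 change of 1.86. Its change was 0.76 in replicates 1 and 2 and 3.10 in replicates 3 and 4 (edgeR adjusted p of the difference 0.00444). NQO1, a quinone reductase, rose from 236.2 ± 111.4 to 363.1 ± 121.4 CPM (SD, n = 4; log2 change 0.69, SE 0.16, edgeR adjusted p = 0.00449), and TXNRD1, a thioredoxin reductase, by a log2 change of 0.68. HMOX1, haem oxygenase 1, rose from 15.7 ± 2.34 to 22.2 ± 3.19 CPM (log2 change 0.49, edgeR adjusted p = 0.0358), but had an adjusted p of 0.0694 with the term for replicates 1 and 2 against 3 and 4. SRXN1 (log2 change 0.30, edgeR adjusted p = 0.321) and GCLM (0.13, adjusted p = 0.581) did not pass, and PRDX1 fell (-0.49), a call lost with that term. AKR1C1 (log2 change 2.85) and AKR1C2 (3.20) rose from below 1 CPM, and the reads of these near-identical genes are uncertain.

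In the inflammatory, integrated stress response, interferon and immediate early lists the members that passed were higher. Of 24 NF-kB targets and cytokines 17 rose and 0 fell (23 and 0 adjusted over the list alone, camera adjusted p = 3.08e-22, adjusted p = 0.486 with an estimated correlation), among them IL1B (1.62 ± 0.52 to 8.04 ± 3.03 CPM, log2 change 2.26). Of 28 targets of ATF4, a transcription factor of the integrated stress response, 16 rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 4.51e-12, adjusted p = 0.486 with an estimated correlation). Those that rose included WARS (log2 change 1.03), STC2 (1.39) and TRIB3 (1.00), of which STC2 and TRIB3 did not pass in DESeq2 with the block. Of 26 interferon-stimulated genes 14 rose and 0 fell (16 and 1 adjusted over the list alone, camera adjusted p = 1.44e-08, adjusted p = 0.486 with an estimated correlation), among them OAS2 (131.7 ± 30.7 to 256.4 ± 56.8 CPM, log2 change 0.97) and MX2 (1.10). Of 21 immediate early genes 6 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 7.41e-07, adjusted p = 0.559 with an estimated correlation), among them FOSL1 (log2 change 1.07) and EGR1 (1.35). With the term for replicates 1 and 2 against 3 and 4, 14 NF-kB targets, 7 ATF4 targets, 8 interferon-stimulated and 5 immediate early genes passed.

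Camera at the preset correlation called a difference in the change between replicates for each of these 4 lists. The median log2 change of NF-kB targets was 0.26 in replicates 1 and 2 and 1.90 in replicates 3 and 4, and that of ATF4 targets 0.09 and 1.07. That of immediate early genes was -0.06 and 0.91, and that of interferon-stimulated genes 0.27 and 0.58. The adjusted p of the difference was 6.44e-42 for NF-kB targets (adjusted p = 0.0216 with an estimated correlation) and 6.06e-42 for ATF4 targets (adjusted p = 0.0211 with an estimated correlation). It was 1.16e-16 for immediate early genes (adjusted p = 0.0391 with an estimated correlation) and 8.30e-05 for interferon-stimulated genes, whose call was lost with an estimated correlation (adjusted p = 0.154). Outside these 4 lists, GDF15, a stress-induced cytokine among the p53 targets, had log2 changes of 0.71 in replicates 1 and 2 and 3.18 in replicates 3 and 4. Those of SLC7A11, one of the NRF2 targets, were 0.76 and 3.10. SLC7A11 had a mean of 98.1 CPM in controls 1 and 2, 8.54 CPM in controls 3 and 4 and 73.3 CPM in treated 3 and 4.

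In the cholesterol synthesis, hypoxia and respiratory chain lists most members that passed were lower. Of 24 cholesterol synthesis genes 16 fell and 0 rose (20 and 0 adjusted over the list alone, camera adjusted p = 1.25e-11, adjusted p = 0.462 with an estimated correlation), with MVK at a log2 change of -0.96 and IDI1 at -0.81. Of 24 hypoxia response genes 11 fell and 1, VEGFA, rose (13 and 3 adjusted over the list alone, camera adjusted p = 1.74e-06, adjusted p = 0.486 with an estimated correlation). The hypoxia list's median log2 change was -0.10 in replicates 1 and 2 and -0.78 in replicates 3 and 4 (camera on the difference, adjusted p = 4.36e-06, adjusted p = 0.0625 with an estimated correlation). CA9 fell by 2.26 on the log2 scale from 2.07 ± 0.34 CPM and P4HA1 by 0.92, while VEGFA, an angiogenic growth factor, had log2 changes of 0.08 in replicates 1 and 2 and 1.55 in replicates 3 and 4 and did not pass in DESeq2 with the block. Of 30 nuclear-encoded respiratory chain genes 15 fell and 0 rose (19 and 0 adjusted over the list alone, camera adjusted p = 1.25e-11, adjusted p = 0.486 with an estimated correlation), with NDUFA2 at -0.84 and COX6C at -0.85. With the term for replicates 1 and 2 against 3 and 4, 11 cholesterol, 9 hypoxia and 7 respiratory chain genes were lower. Under total counts with the block 10 cholesterol, 10 hypoxia and 12 respiratory chain genes were lower, and 3 hypoxia genes were higher. Changes also followed gene length. The shortest 10% of genes had a median log2 change of -0.19 and the longest 10% one of 0.18. Across genes, which are not independent replicates, the Spearman correlation of change with length was 0.246, 0.302 and 0.228 in pairs 1 to 3 and 0.0141 in pair 4. With a correction for principal transcript length 11 respiratory chain genes were lower, and the list's median log2 change was -0.375 in place of -0.46.

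Members of the cell cycle, heat shock and peroxide lists also changed. Of 30 G2/M genes 6 fell, among them PTTG1 and BIRC5, and 1, MKI67, rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.00172, adjusted p = 0.629 with an estimated correlation). Under total counts 2 G2/M genes were lower and 1 higher, with a median log2 change of -0.13 against -0.24. The G2/M median log2 change was 0.03 in replicates 1 and 2 and -0.49 in replicates 3 and 4 (camera on the difference, adjusted p = 3.92e-08, adjusted p = 0.0788 with an estimated correlation). MKI67, a proliferation marker, went from 162.8 ± 42.2 to 237.3 ± 93.0 CPM (edgeR adjusted p = 0.0367). Its call and those of PTTG1 and BIRC5 were lost with the term for replicates 1 and 2 against 3 and 4, which left 0 G2/M genes higher and 1 lower. That term left 3 heat shock genes lower, and 1 peroxide and superoxide enzyme higher and 2 lower. Of 21 heat shock genes 5 fell and 0 rose (5 and 0 adjusted over the list alone), among them HSPE1 (log2 change -0.75). The list passed camera with the block (adjusted p = 0.0137, adjusted p = 0.629 with an estimated correlation) and not without it (adjusted p = 0.189), and its median was 0 under total counts. That median log2 change was 0.13 in replicates 1 and 2 and -0.44 in replicates 3 and 4 (camera on the difference, adjusted p = 1.14e-05, adjusted p = 0.189 with an estimated correlation). Of 21 other peroxide and superoxide enzymes 6 fell, among them MSRB1 (-0.71), and SOD2, the mitochondrial superoxide dismutase, rose (0.75; 8 and 2 adjusted over the list alone, camera adjusted p = 0.00237, adjusted p = 0.486 with an estimated correlation). With the correction for principal transcript length that list did not pass camera (adjusted p = 0.0622). Of 30 S phase genes 2 rose and 1 fell (2 and 1 adjusted over the list alone). All 3 tested metallothioneins fell (3 adjusted over the list alone), among them MT1F (log2 change -0.79), a family whose members share reads. Of the single genes, CAT (log2 change -0.30, edgeR adjusted p = 0.187), HK2 (0.32, adjusted p = 0.132) and ARRDC4 (0.38, adjusted p = 0.0625) did not pass. CDKN1A, a cell cycle inhibitor, rose (0.62). TXNIP rose (0.56), a call lost with the term for replicates 1 and 2 against 3 and 4.

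The mitochondrially encoded list passed camera with the block (adjusted p = 0.0235, adjusted p = 0.677 with an estimated correlation) and not without it (adjusted p = 0.125). Of its 13 members 1, MT-ND4L, rose (1 adjusted over the list alone), a call lost with the term for replicates 1 and 2 against 3 and 4. Under total counts with the block 4 members were higher. MT-ND4L was at 40.2 CPM in control 1 and at 143.2 to 245.9 CPM in the other controls, and its call was also lost without replicate 1 (adjusted p = 0.248). The share of counts in mitochondrially encoded genes was 1.234% in control 1 and 2.21 to 3.284% in the other libraries. The list's median log2 change was 1.395 in pair 1, 0.5955 in pair 2, -0.2787 in pair 3 and -0.212 in pair 4. It was 0.90 in replicates 1 and 2 and -0.20 in replicates 3 and 4 (camera on the difference, adjusted p = 1.51e-09, adjusted p = 0.208 with an estimated correlation).

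Urothelial markers moved both ways. Of 18 basal and squamous markers 5 rose, among them LAMB3 (2.30-fold) and TGM1 (log2 change 1.25), and 3 fell, among them KRT5 (-0.75) and KRT14 (-0.66; 6 and 3 adjusted over the list alone). In edgeR with the term for replicates 1 and 2 against 3 and 4, 3 of these markers were higher and 3 lower. Of 14 luminal markers 2 rose, FOXA1 (log2 change 0.92) and GATA3 (0.52), and 2 fell, KRT19 (-0.87) and KRT8 (-0.58; 2 and 2 adjusted over the list alone). GATA3 (adjusted p = 0.0614) and KRT8 (adjusted p = 0.0998) lost their call in edgeR with the term for replicates 1 and 2 against 3 and 4. Of 17 mesenchymal markers 2 rose, TNC and SNAI1, and 6 fell, among them LOXL2 (log2 change -0.95; 2 and 7 adjusted over the list alone). With that term 0 mesenchymal markers were higher and 5 lower, with TNC at an adjusted p of 0.124 and SNAI1 at 0.0676. Of the markers of cells that the culture should not hold, 0 of 4 fibroblast and 0 of 3 endothelial markers passed, and of 4 leukocyte markers CD74 rose and CSF1R fell (1 and 1 adjusted over the list alone). CD74 had an adjusted p of 0.0698 with that term.

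The remaining 9 lists did not pass camera. The numbers that rose and fell were 6 and 4 of 29 for p53 targets (9 and 6 adjusted over the list alone), 3 and 0 of 26 for autophagy and lysosome (3 and 0), 2 and 1 of 15 for the BCL2 family (2 and 1), 1 and 2 of 23 for base excision repair (1 and 3) and 2 and 1 of 22 for cell junctions (3 and 1). They were 3 and 2 of 22 for ER chaperones (3 and 2 adjusted over the list alone), 0 and 0 of 14 for fatty acid synthesis (0 and 0), 1 and 4 of 23 for glycolysis (1 and 6) and 2 and 1 of 20 for TGF-beta and YAP targets (2 and 1). With the term for replicates 1 and 2 against 3 and 4, 3 p53 targets were higher and 1 lower, and each of the other 8 lists had at most 1 member in either direction. Camera at the preset correlation called a difference between replicates 1 and 2 and replicates 3 and 4 for fatty acid synthesis (adjusted p = 0.00361), glycolysis (adjusted p = 0.0265) and p53 targets (adjusted p = 0.0346). These were lost with an estimated correlation (adjusted p = 0.483, 0.170 and 0.280). The S phase, basal, luminal and mesenchymal lists did not pass camera either. With a length correction the mesenchymal list was called lower (adjusted p = 0.0226 with principal transcript length, 0.0347 with summed exon length), as was the glycolysis list with summed exon length (adjusted p = 0.0242). No list passed camera on the treatment effect with an estimated correlation, with or without the block.

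**Figure D3:**
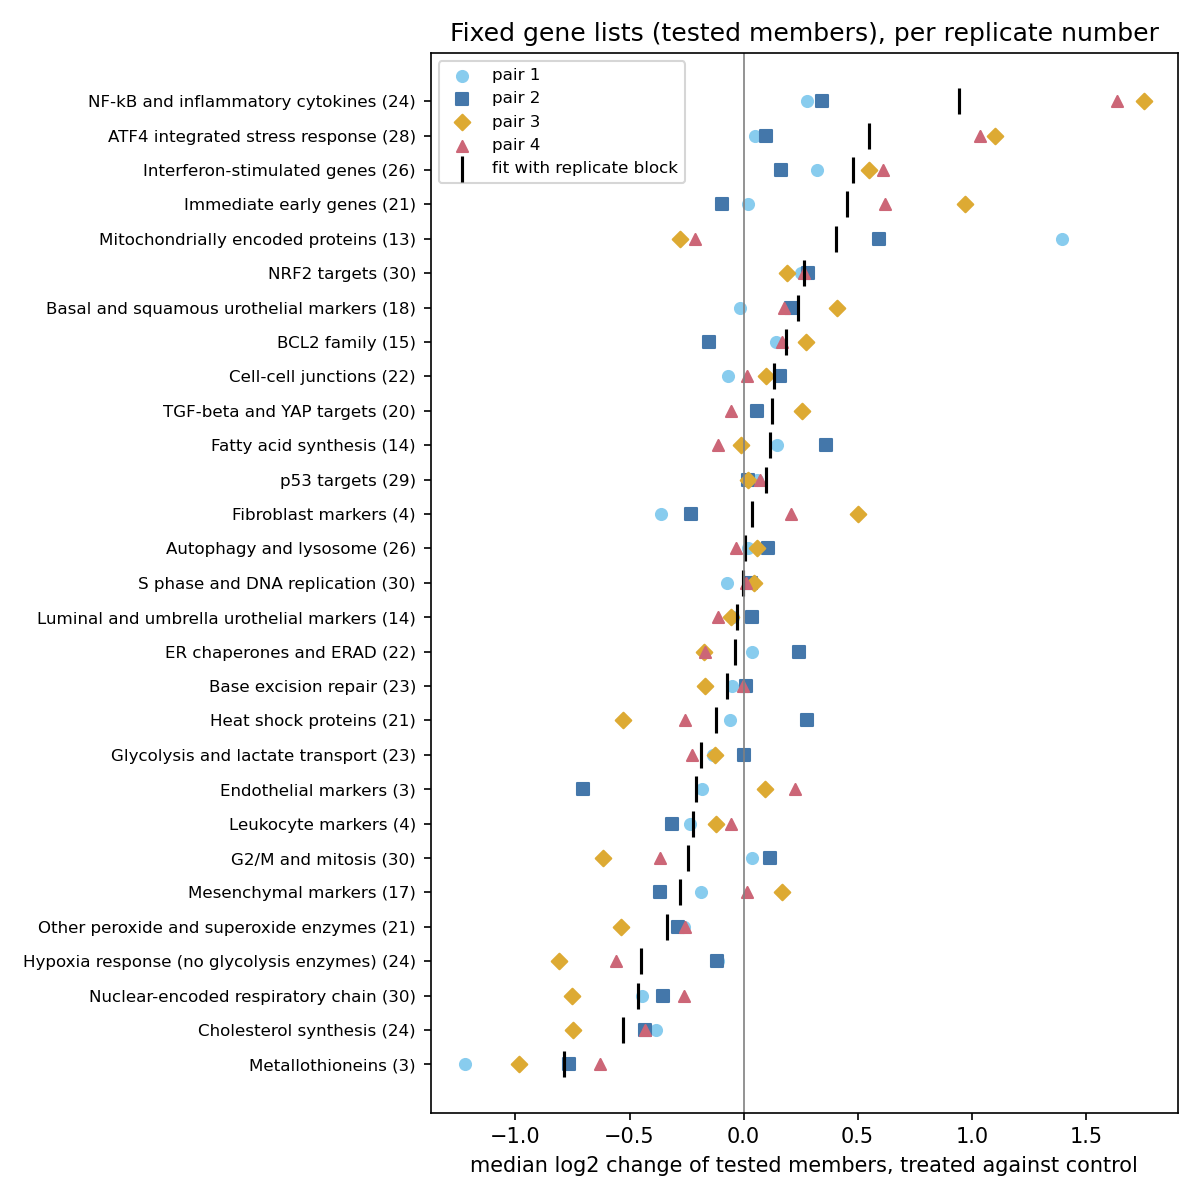
Median log2 change (treated against control, x axis) of the tested members of each fixed list (number in brackets) in each of the 4 pairs of equal replicate number (coloured points) and in the fit with the replicate block (black bars). NF-kB targets have pair medians of 0.28, 0.34, 1.75 and 1.64; the blocked medians of base excision repair, ER chaperones, luminal and S phase genes turn positive under total counts, and that of autophagy genes negative under size factors.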

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

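The division into replicates 1 and 2 and replicates 3 and 4 was found from expression, and the count over other halvings of the numbers and the correction for summed exon length were chosen after their results were seen.

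In edgeR the effect of treatment differed past an adjusted p of 0.05 for 37 genes with a higher log2 change in replicates 3 and 4 and 3 with a lower one. These counts go by sign, so a gene that fell further in replicates 3 and 4 counts as lower. Among named genes the log2 effect in replicates 3 and 4 exceeded that in replicates 1 and 2 by 3.57 for IL1A, 2.48 for GDF15, 2.34 for SLC7A11, 2.33 for STC2, 1.70 for DUSP5, 1.68 for SESN2 and 1.47 for VEGFA. IL1A was at 44.4, 61.1, 5.31 and 5.91 CPM in controls 1 to 4 and at 133.5, 103.0, 172.6 and 126.9 CPM in treated 1 to 4. Mean control levels were also lower in replicates 3 and 4 for STC2 (69.6 against 1134 CPM) and SLC7A11 (8.54 against 98.1 CPM). The same held for VEGFA (18.3 against 112.8 CPM) and DUSP5 (10 against 36.7 CPM). For STC2, SLC7A11 and VEGFA treated 3 and 4 stayed below controls 1 and 2 (means 412.1, 73.3 and 53.6 CPM). For IL1A and DUSP5 they lay above.

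Within replicates 3 and 4 edgeR called 234 genes higher and 93 lower, and within replicates 1 and 2 it called 12 higher and 20 lower. An exchange of control and treated libraries within a pair is argued against as the source of the difference in effects, since 82% of the 327 genes called in replicates 3 and 4 moved the same way in pair 1 and 82% in pair 2. A trend with summed exon length is argued against too, with 39 of the 40 genes still called after that correction. This check did not use principal transcript length. Other ways of halving the 4 numbers gave at most 0 genes against 40. They mix replicates 1 and 2 with 3 and 4, whose separation then adds to the spread, so they could hardly call any gene. The 3 ways (1 of them the real one) are also too few for a share under 0.05. An unlabelled difference between the cultures or their handling may account for it and stays open, and no biological explanation was tested.

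The fall of respiratory chain genes was weighed against the length trend. A correction for summed exon length left the list's median log2 change at -0.46, but that length measures these genes' main transcripts poorly (median 3309.5 bases against 1515 for the principal transcript) and left a correlation of 0.113 between change and principal length across genes. With principal transcript length, which left 0.000902, the median was -0.375 and camera still called the list at the preset correlation (adjusted p = 9.8e-10), a call that without the length correction was lost with an estimated correlation (adjusted p = 0.486). Of 10000 random lists matched on transcript length and abundance, 0% had a median as low as -0.461, with a random median of -0.211. The random lists drew each gene independently, so their spread leaves out any shared variation of respiratory chain genes and the percentile cannot decide the question. The trend as fitted may account for part of the fall, and it left a median of -0.375. Whether that remainder exceeds chance, and whether it is an effect of the treatment, stays open.

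Of 258 groups of 4 libraries, 3 held a library far from the other 3, where chance gives about 12.9 for independent libraries. The separation of replicates 1 and 2 from 3 and 4 breaks that assumption, so the 2 numbers cannot be compared. ID4 was at 34.5 CPM in treated 2 and at up to 74.9 CPM in the others (gap over range 0.878). CGN was at 35.1 CPM in treated 2 against 22.2 to 22.5 CPM (0.979), and CA9 at 0.849 CPM in treated 4 against 0.294 to 0.362 CPM (0.878).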

How the results depend on the processing

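The alternatives to the blocked fit and to the difference between replicates were chosen after the data were seen. The log2 changes of SCD, CDH5, COL1A1, EGFL7 and PDGFRB, which passed in no fit, changed sign under some alternatives (SCD from -0.04 to 0.09 under total counts). No other named gene changed sign. The share of blocked calls that were higher, 51.9%, was 48.2% with size factors, 48.1% with DESeq2 and 46.4% with the correction for summed exon length. The medians of 5 lists that were not called changed sign with the scaling (base excision repair, ER chaperones, luminal, S phase and autophagy). Without a block, edgeR called 0 genes under size factors, total counts, a minimum mean of 1 CPM, protein-coding genes only, a threshold of 0.01, mitochondrial and abundant genes left out, and each library left out; limma-voom and both FPKM scales also gave 0. With no filter 16 named genes passed, 18 genes were higher and 16 lower, all of them at least 2-fold (18 and 16), and DESeq2 gave 35 and 39 (24 and 24 at least 2-fold). The replicate block gave 1308 and 1213 (169 and 159 at least 2-fold) and 114 of the 125 named genes their call; it changed no list call but those of heat shock and mitochondrially encoded genes. Leaving out a library without the block moved the number of lists lower from 5 to between 2 (control 3, control 4 or treated 1 left out) and 6, with 3 without treated 2. Camera with an estimated correlation gave 0 lists higher and 0 lower with and without the block; fry gave 0 and 0 without it and 1 and 0 with it. The NRF2 median of 0.276 then lost its call in both tests, and the blocked median of 0.265 lost it in camera only. Leaving out a library without the block moved the NRF2 median to between 0.182 (treated 4 left out, camera adjusted p = 0.00277) and 0.311 (treated 1 left out), with its call kept. Against the blocked counts, total counts gave 535 genes lower and 83 at least 2-fold lower, and the term for replicates 1 and 2 against 3 and 4 gave 648 and 534, with 32 named genes losing their call. Leaving out a pair gave 593 (without replicate 3) to 978 genes higher (864 without replicate 2) and 507 (without replicate 3) to 908 lower (717 without replicate 1, 638 without replicate 2); 3 (without replicate 3) to 7 lists were lower, against 6. With DESeq2 and the block 11 named genes lost their call (TRIB3, STC2, CLDN1, SYVN1, CRELD2, PFKM, VEGFA, SNAI1, MT-ND4L, SESN2 and HMOX1) and AKR1C2 had no adjusted p. Correcting for principal transcript length gave 900 and 1052 and took the call from 21 named genes. Pairing treated 3 with control 4 and treated 4 with control 3 gave 1421 and 1358. Log2 changes higher in replicates 3 and 4 than in replicates 1 and 2 numbered 79 with DESeq2 against 37. Lower ones numbered 15 with DESeq2 and 1 with size factors against 3. The cause was not tested for any of these shifts. On simulated counts of this depth, with pairing by number built in and the spread of the blocked fit, edgeR without a block recovered 0% of 2-fold changes. DESeq2 without a block recovered 40.3%.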

Other observations

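Other splits of the libraries were counted for each fit. Without the block, 35 of the 35 splits gave at least the 0 genes of the real split, higher or lower, 2-fold or not, which any split must, so that count says nothing about chance. The split of replicates 1 and 2 from replicates 3 and 4 gave up to 3315 genes in a direction and 1221 at least 2-fold, which points to a structure of the samples, and the blocked counts are the ones to set beside it. For lists, 21 of the 35 splits gave at least the 5 of the real split in either direction (highest other 9), so chance cannot be excluded for the number of lists. With the block, the 8 exchanges of groups within pairs are too few for a share under 0.05. The real one gave 1308 genes higher, 1213 lower, and 169 and 159 at least 2-fold, and the highest other gave 0 in each case (1 of 8 as large). For lists with the block, 3 of the 8 exchanges gave at least the real 6 (highest other 9).

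Against 10000 random lists matched on transcript length and abundance, as a description of these libraries, the median log2 change of the heat shock list (-0.123) lay at percentile 35.49. That of 20 other peroxide and superoxide enzymes (-0.32) lay at percentile 5.63, and that of the glycolysis list (-0.185) at 4.96. The median of the G2/M list (-0.244) lay at percentile 0.69. Of other lists that did not pass camera with the block, the mesenchymal median (-0.277) lay at 0.24, the basal one (0.241) at 99.78, that of the BCL2 family (0.188) at 99.66 and that of p53 targets (0.099) at 97.38. Cholesterol synthesis, hypoxia and respiratory chain medians lay at 0. Those of NF-kB, ATF4, interferon, immediate early, NRF2 and mitochondrially encoded genes lay at 100. The other lists lay between 37.82 and 93.47.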
